A study of Mus musculus with 6 samples.

How the data were processed

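Single arrays were made from bone marrow cells of 3 wild-type and 3 p65 knockout mice, sorted as negative for lineage markers and Flk2 and positive for Sca-1 and c-kit. Per the labels' protocols, cells were sorted straight into lysis buffer, RNA was extracted with a Qiagen RNeasy kit, and it was amplified and labelled with the NuGEN Ovation Pico WTA V2 system, a whole-transcriptome amplification for small amounts of RNA. Such amplification can change the range of signals from one sample to the next. The submitters' processing notes name RMA, Affymetrix Expression Console and Partek, without versions. RMA subtracts background, normalizes between arrays and summarises probes on the log2 scale. The authors deposited 1 table of log2 expression values for the 6 arrays, and it is the only table used here. The design text names the Mouse Exon 1.0 ST array and another program for exon arrays, while the probe annotation given for the table is that of the Mouse Gene 1.0 ST array. The table's rows were named through that annotation, and which description holds for the scanning was not settled here. Whether the deposited values had been normalized across all 6 arrays together is not given in the sources used here. The array medians (5.72 to 5.98) and SDs (2.03 to 2.29) differ, so the columns are not quantile-matched over all rows. Scanner files were not used here.

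The table has 35557 rows. Of these, 21789 have 1 gene symbol in the annotation, 1621 have several and 12147 have none listed. Gene identifiers of 21698 of the single-symbol rows were found in a RefSeq gene table of the mouse assembly GRCm38.p6, and 0 symbols needed an update. Rows with 1 symbol were used, and for the 999 genes with more than 1 row the row with the highest mean over all arrays was kept, which left 19938 genes. No array was left out, 0 columns were unassigned and no arrays held identical values. Groups and replicate numbers come from the sample labels, which describe each sample as 1 mouse. Of the sex-linked check genes, Xist lay between 10.1 and 10.8 in all 6 arrays and Eif2s3y between 2.29 and 2.50, and the list's mean log2 fold change was -0.08, with 0 of 4 measured members past the threshold.

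Knockout was compared with wild-type in limma 3.58.1 (R 4.3.3) with group as the only term, 4 residual degrees of freedom, a two-sided moderated test and Benjamini-Hochberg adjustment over all genes at 0.05. Fold changes are knockout over wild-type. The lists of genes, 28 in number plus the sex-linked genes, held 1011 entries, of which 903 were measured. They were tested with camera at a preset correlation of 0.01, adjusted over the 28 lists, and beside it with an estimated correlation and with fry. Single members were counted both over all genes and adjusted over the list alone. The named genes were fixed by rule before the data were examined. They are the 15 higher and 15 lower genes with the largest changes among those past the threshold without overlap between groups, up to 6 members of each list with the smallest p among those past either threshold (or 2 members otherwise), and the NF-κB subunit and sort genes. Predicted genes, olfactory and vomeronasal receptor genes and small RNA genes were left out of the largest changes, which removed 6 called genes from consideration.

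Whether replicate numbers pair the mice across groups was checked through the correlation of each array's deviations from its group mean. Same-numbered arrays gave 0.368, 0.119 and 0.162, all above the minimum of 0.1 set for pairing, so values with the number as a block are given where they change a call or move a count by over 1.5 times. Differently numbered arrays 2 and 3 correlated as strongly (0.183 and 0.195), so arrays 2 and 3 do not each correlate best with their own number, and the labels do not state what a number marks. Array weights, computed by limma, were 0.116 for wild-type replicate 1 and 0.935 to 2.2 for the others. The first principal component held 65.4% of the variance. Wild-type replicate 1 lay at -72.1, wild-type replicates 2 and 3 at 0.209 and -1.11, and the knockouts between 17.7 and 28.3.

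The test was checked on simulated arrays with the means, variances and array weights of these 19938 genes, with 200 genes changed. In 5 runs it recovered 56% of the 100 genes changed by 1 on the log2 scale and 96.2% of the 100 changed by 2, with 0.8 false calls per run and 0 calls of the wrong sign. A simulated list of 30 genes shifted by 0.5 was called in 5 of 5 runs, and an unshifted one in 0. These simulated genes vary independently, so they say nothing of the correlation between genes of a list. They also carry no difference in signal range between groups and no trend with expression level. The false calls therefore do not give the error rate of the real comparison.

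Alternatives fixed in advance were the replicate block, quantile normalization, centring arrays on their medians, leaving out dim genes, an intensity trend, robust variance estimation, array weights, averaging the rows of a gene, an ordinary per-gene test, a fold minimum, all rows of the table, other list tests and leaving out each array. Cyclic loess normalization, list member counts and camera with an estimated correlation without wild-type replicate 1, and 10000 random lists matched on mean expression (each member replaced by a gene within 100 ranks) were added after the data were seen. Figures were drawn with matplotlib 3.10.9.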

Results

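Gene expression was measured on Affymetrix arrays in bone marrow cells of 3 wild-type mice and 3 mice labelled as p65 knockout. The protein p65, also named RelA, is a subunit of the transcription factor NF-κB. The sample titles do not state in which tissues its gene was deleted. The cells had been sorted as negative for lineage markers and Flk2 and positive for c-kit and Sca-1, a gate that enriches for hematopoietic stem cells and early progenitors. The design has 1 comparison, knockout against wild-type, which asks which transcripts differ in these cells between the genotypes. Each mouse gave 1 array, and 19938 genes were compared on the log2 scale. The number of arrays limits the precision. Median log2 signal per array ran from 5.72 to 5.98. Wild-type replicate 1 stood apart from the other arrays. Its values had an SD of 2.03, against 2.22 to 2.29 in the others, and it correlated with them at r = 0.924 to 0.943, against 0.974 to 0.989 among the rest. Signal range also separated the groups. The SDs were 2.03, 2.22 and 2.22 in wild-type and 2.26, 2.29 and 2.28 in knockout. The medians were 5.98, 5.81 and 5.84 in wild-type and 5.75, 5.72 and 5.72 in knockout. Range and genotype thus go together in these arrays.

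The deleted gene was examined first. Rela averaged 7.77 ± 0.22 (SD, n = 3) in wild-type and 7.39 ± 0.08 (SD, n = 3) in knockout cells on the log2 scale, a log2 fold change of -0.39 (SE 0.16). Every knockout value of Rela lay below every wild-type value, and the two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 arrays allow. The difference did not pass the threshold over all genes (limma adjusted p = 0.209). Without wild-type replicate 1 the log2 fold change of Rela was -0.51 and its limma adjusted p was 0.04, within a range of 0.0292 to 0.486 over 16 alternatives. Probes outside the deleted part of the gene can keep their signal, so the level of Rela is a weak check of the labels. The log2 fold changes of the other subunit genes were -0.30 for Relb, 0.26 for Rel and 0.04 for Nfkb2, none past the threshold, and the sign of Rel and of Nfkb2 turned without wild-type replicate 1. Nfkb1 and the Sca-1 gene Ly6a were not analysed here. Among the other genes that relate to the sort, Kit (the c-kit receptor) had a log2 fold change of -0.30 (limma adjusted p = 0.327), Flt3 (the Flk2 receptor) of 0.06 and Cd34 of 0.04. The last 2 values turned negative under quantile and cyclic loess normalization. Kit ran from -0.55 to -0.16 over 16 alternatives (limma adjusted p from 0.0465 to 0.688) and stayed on the same side of the threshold in 14. Without wild-type replicate 1 it was -0.48.

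In all, 163 genes passed limma at an adjusted p under 0.05, 137 higher and 26 lower in knockout. Of 32 measured genes in a list of the myeloid lineage 12 rose, 0 fell and 20 did not pass, and the list passed camera with a preset correlation but not with an estimated one (adjusted p = 0.434). The largest rise was that of Elane, which encodes neutrophil elastase, from 7.02 ± 0.38 to 11.0 ± 0.15 (SD, n = 3 each), or 15.8-fold. Bub1, a mitotic checkpoint kinase gene, rose 2.22-fold. It is 1 of 7 cell cycle genes that rose, while 52 of the 59 measured did not pass and that list did not pass with an estimated correlation (camera adjusted p = 0.63). Plag1, a zinc finger transcription factor gene, fell the most, by 2.00 on the log2 scale (SE 0.22), and the stem cell transcription factor gene Hlf was also among the lower genes.

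Of the 15 genes with the largest rises, several encode proteins of neutrophil and monocyte precursors. Hp, the gene of haptoglobin, rose by 3.86 on the log2 scale (SE 0.19, limma adjusted p = 0.00027), and Ms4a3, a gene of granulocyte-monocyte progenitors, rose by 3.48 (SE 0.23). Ctsg, the cathepsin G gene, rose by 2.80 (SE 0.15), and Lcn2, the lipocalin 2 gene, by 2.71 (SE 0.24). Clec12a, Trem3, Ly86, Ms4a6c and Atp8b4 rose by 2.50 to 3.07. Ccr2, a chemokine receptor gene of monocytes, rose by 2.53, F13a1 by 2.50 and Anxa3 by 3.06. Fcer1a, which encodes the alpha chain of the high-affinity IgE receptor, had a signal of 4.10 in wild-type and 7.16 in knockout. Ifi209, a gene of the interferon-inducible p200 family, had 4.06 and 7.32, with a wide spread in knockout (SD 0.96). Their wild-type signals were close to that of the Y-linked gene Kdm5d (4.15) in these arrays of high Xist and are not shown to lie above background, so the sizes of both rises are uncertain.

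The lower genes changed less. Hlf fell by 1.27 on the log2 scale (SE 0.22, limma adjusted p = 0.0485), and Tox, which encodes an HMG-box protein, fell by 1.51 (SE 0.17). The imprinted noncoding RNA gene Meg3 fell by 1.10, and Cish, which encodes an inhibitor of cytokine signalling through STAT5, by 1.08. Lrrn4, Mageh1, Adam22, Tgm2, Crispld1, Sdc2, Klhl4, Tns2, Fstl1 and Gimap8 fell by 0.99 to 1.27, where Sdc2 had a knockout signal (3.78) below that of Kdm5d. For each of the 163 genes the 3 knockout values lay on one side of all 3 wild-type values. Of all genes, 34.6% showed such a separation, where chance gives 10%. Array SDs and medians also separate the groups, and fold changes vary with expression level. This excess therefore does not by itself show an effect of p65.

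**Figure D1:**
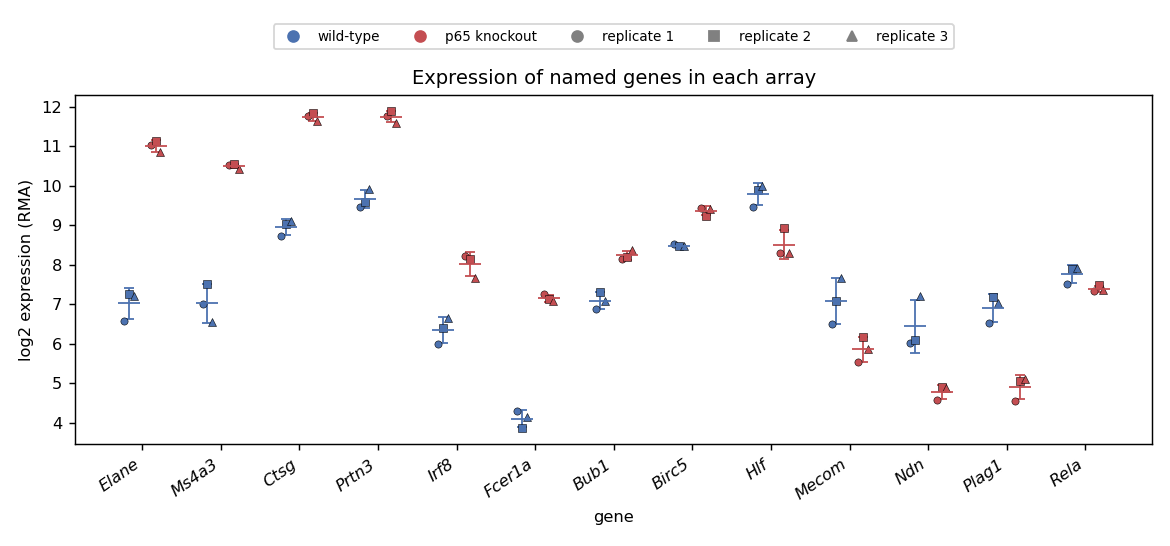
Log2 expression of named genes in each of the 6 arrays, with wild-type in blue and p65 knockout in red, marker shapes for the replicate numbers, horizontal bars for group means and error bars for the SD (n = 3). Elane lies near 7 in wild-type and 11 in knockout, while Rela differs by 0.39; Mecom, Ndn and Rela did not pass the threshold over all genes.

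With the replicate number as a block, 372 genes passed (282 higher and 90 lower), and 162 of the 163 genes were among them. Without wild-type replicate 1, 929 genes passed (653 higher and 276 lower), and all 163 were among them. Leaving out any other array reduced the count, to 75 without wild-type replicate 2, 26 without wild-type replicate 3, and 22, 21 and 29 without knockout replicates 1, 2 and 3. Higher genes made up 84% of calls on the deposited values. They made up 96.9% with arrays centred on their medians (186 higher, 6 lower), which adds 0.146 to the log2 fold change of every gene and so leaves differences between genes as they were. With cyclic loess normalization they made up 68% (149 higher, 70 lower). A fold of at least 1.5 at an unadjusted limma p under 0.01 was met by 1113 genes, 879 higher and 234 lower. The unadjusted criterion alone was met by 1466 genes, where chance gives 199. Signal range differs between the groups, so this excess does not by itself show an effect of p65. An unadjusted p under 0.05 was reached by 4309 of all 19938 genes. Counts of list members at that level, given below, are to be read against this share.

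Fold changes varied with expression level across genes, which are not independent replicates. Spearman's rho between log2 fold change and mean expression was 0.634, and 0.379 without wild-type replicate 1. The median log2 fold change was -0.22 among the dimmest genes, -0.09 among those of intermediate expression and 0.30 among the brightest, in equal groups. Without wild-type replicate 1 these medians were -0.09, -0.08 and 0.13. This trend runs alongside every gene group described here.

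**Figure D2:**
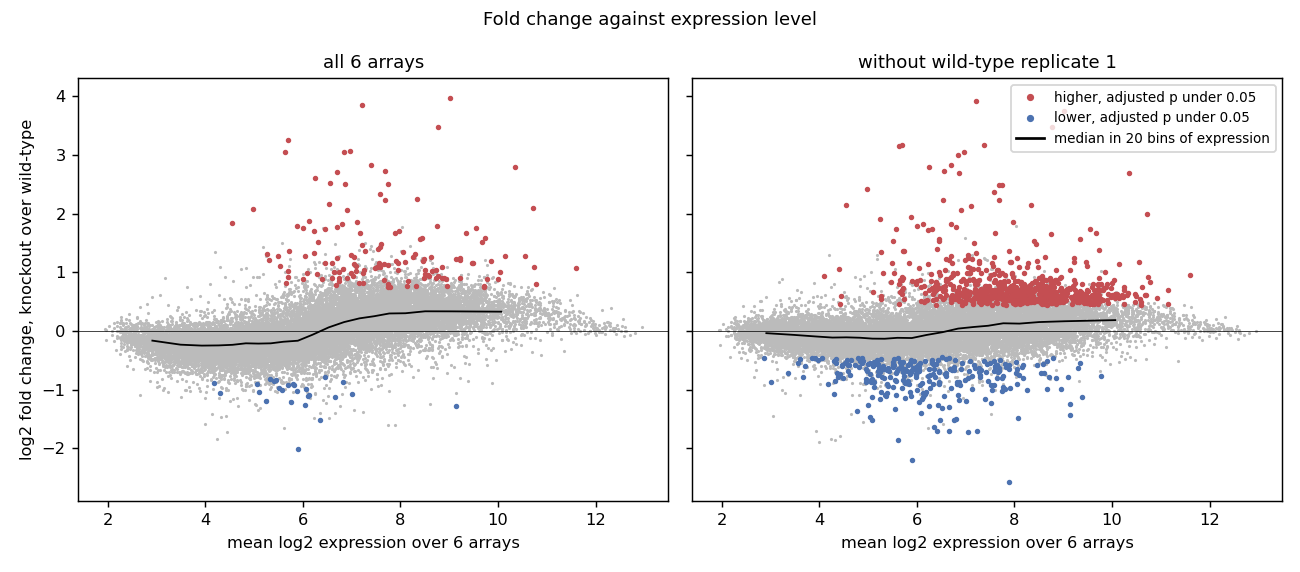
Log2 fold change of knockout over wild-type (vertical axis) against mean log2 expression over 6 arrays (horizontal axis) for 19938 genes, with all arrays at left and without wild-type replicate 1 at right. Coloured points passed an adjusted p under 0.05 and the black line joins medians of genes of similar expression; it climbs from dim to bright genes in both panels, more steeply at left.

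Of 28 gene lists fixed before the data were examined, 15 shifted against other genes at a camera adjusted p under 0.05 with a preset correlation, 12 higher and 3 lower in knockout. With a correlation estimated from the arrays none passed (lowest adjusted p = 0.434). The directional fry test, which does not compare a list with other genes, passed for 1, the myeloid lineage. Each list's mean was also ranked among 10000 random lists matched on mean expression. Random genes are drawn independently while genes of a list vary together, so these percentiles are descriptive and not p-values. The two-sided exact permutation test of a list's array means cannot give p below 0.1.

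The myeloid lineage list had a mean log2 fold change of 1.06 over 32 measured members (camera adjusted p = 1.16e-13; adjusted p = 0.434 with an estimated correlation). Of these members 12 rose and 0 fell, and 20 did not pass. Adjusted over the list alone, 21 rose. Prtn3, the proteinase 3 gene, rose 4.26-fold and Anxa3 8.31-fold. The list's array means, each relative to the average of all 6 arrays, were -0.61, -0.47 and -0.51 in wild-type and 0.54, 0.65 and 0.40 in knockout. Without wild-type replicate 1 the mean was 1.02, with 16 members higher. The list of mast cell, basophil and eosinophil genes had a mean of 0.63 and a median of 0.32 over 19 members (camera adjusted p = 0.00227; adjusted p = 0.63 with an estimated correlation). Fcer1a, Ms4a2 (the beta chain of the same receptor, 3.32-fold) and Hdc (histidine decarboxylase, 3.16-fold) rose, and 5 members did adjusted over the list alone or with the replicate block.

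The lists of macrophage and granulocyte, lymphocyte and stroma markers did not rise with the myeloid list. Cxcr2, a chemokine receptor gene of neutrophils, is in none of them, had a log2 fold change of 1.14 and rose with the replicate block (limma adjusted p = 0.0211). The list of macrophage and granulocyte markers had a mean of -0.22 over 20 members (camera adjusted p = 0.0414; adjusted p = 0.715 with an estimated correlation), and 0 members passed limma singly over all genes or adjusted over the list alone, where 4 had an unadjusted p under 0.05. Its mean lay at percentile 3.27 of the matched random lists, inside their central 95%. The call was kept under 10 of 19 alternatives and was lost without wild-type replicate 1 (mean -0.09, camera adjusted p = 0.421), knockout replicate 1 (-0.23) or knockout replicate 2 (-0.14). It was also lost without the dimmest genes (-0.15), under quantile (-0.11) and cyclic loess normalization (-0.13) and with array weights (-0.13). The list of B, plasma, T and NK cell markers had a mean of -0.36 over 15 members (camera adjusted p = 0.0104; adjusted p = 0.715 with an estimated correlation), again with 0 members past limma over all genes, 6 at an unadjusted p under 0.05, and 1 lower, Cd3d (log2 fold change -0.57), adjusted over the list alone. Cd3d had a knockout signal of 4.06, below the wild-type signal of Kdm5d (4.15), so the size of its fall is uncertain. The list's camera call was kept under 14 of 19 alternatives. It was lost without the dimmest genes, where the mean was -0.12 (camera adjusted p = 0.147), without wild-type replicate 1 (-0.26, camera adjusted p = 0.0504) and with cyclic loess normalization (-0.24). Stroma and endothelium markers had a mean of -0.16 over 21 members and did not pass camera (adjusted p = 0.145), with means of -0.10 without wild-type replicate 1, -0.05 under quantile and -0.06 under cyclic loess normalization. None of them passed limma, 3 had an unadjusted p under 0.05, and Emcn (log2 fold change -1.48) fell with the replicate block.

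The cell cycle list had a mean log2 fold change of 0.62 over 59 members (camera adjusted p = 3.79e-21; adjusted p = 0.63 with an estimated correlation), and 58 members were positive. Over all genes 7 members rose and 0 fell, and adjusted over the list alone 42 rose. Bub1, Aurkb (a mitotic kinase gene, 1.86-fold), Birc5 (survivin, 1.85-fold) and Ccnb2 (cyclin B2, 1.84-fold) were among the 7. The count was 14 with the replicate block and 22 without wild-type replicate 1, and the list's mean was 0.37 with cyclic loess normalization. The respiratory chain list had a mean of 0.49, with 51 of 51 members positive (camera adjusted p = 1.22e-17; adjusted p = 0.63 with an estimated correlation). None of its members passed limma over all genes, while 40 had an unadjusted p under 0.05 and 33 rose adjusted over the list alone. Cycs, the cytochrome c gene, had a log2 fold change of 0.91 and Cox5a of 0.75. The replicate block gave 1 call in this list and leaving out wild-type replicate 1 gave 9. The mean fell to 0.26 under quantile and 0.23 under cyclic loess normalization.

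Interferon-stimulated genes had a mean of 0.63 and all 44 members were positive (camera adjusted p = 2.57e-09; adjusted p = 0.715 with an estimated correlation). Only Gbp3, a guanylate-binding protein gene, rose over all genes or adjusted over the list alone (2.63-fold). Knockout replicate 1 set much of this mean. The list's array means were 0.96, 0.13 and -0.14 in the knockouts and -0.59, -0.20 and -0.15 in wild-type, and without knockout replicate 1 the mean log2 fold change was 0.31 (camera adjusted p = 7.97e-05). The MHC class I presentation list had a mean of 0.46 over 17 members (camera adjusted p = 2.81e-06; adjusted p = 0.63 with an estimated correlation), with 0 members past limma over all genes, 12 at an unadjusted p under 0.05, 11 higher adjusted over the list alone, and 3 higher without wild-type replicate 1. Psmb10 (log2 fold change 0.83) and Psmb8 (0.72), genes of immunoproteasome subunits, had the highest values named. The class I genes H2-K1, H2-D1, H2-T23, H2-T22 and H2-Q7, also listed, were not measured, so this mean does not cover them. The list's mean was 0.25 under quantile and 0.20 under cyclic loess normalization. MHC class II presentation had a mean of 0.39 over 9 members (camera adjusted p = 0.0414; adjusted p = 0.715 with an estimated correlation), and H2-Ab1 rose 2.04-fold while 2 members rose adjusted over the list alone. The list's mean lay at percentile 97.3 of the matched random lists, inside their central 95%. Its call was kept under 11 of 19 alternatives and was lost without wild-type replicate 1 (mean 0.25), wild-type replicate 2 (0.43) or knockout replicate 1 (0.31).

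**Figure D3:**
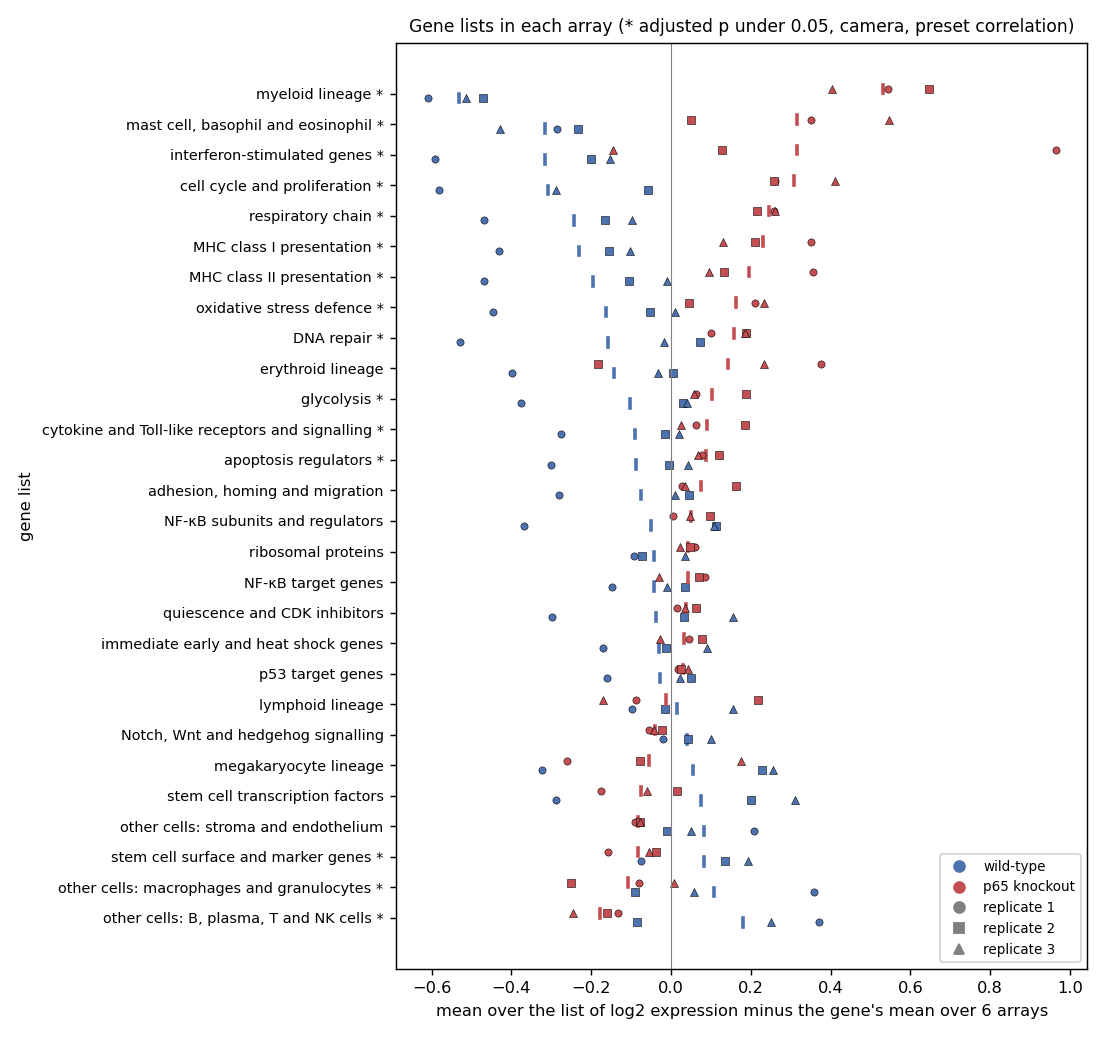
Mean over each list of log2 expression minus the gene's average over 6 arrays (horizontal axis), per array, for the 28 gene lists (vertical axis), with wild-type in blue, p65 knockout in red and vertical bars at group means. The myeloid list separates the groups by 1.06; wild-type replicate 1 (blue circles) lies apart from the other wild-type arrays in many lists, and knockout replicate 1 leads the interferon list at 0.96.

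Stem cell surface and marker genes were lower as a list. They had a mean of -0.17 over 35 members (camera adjusted p = 0.0414; adjusted p = 0.715 with an estimated correlation). Its 1 call over all genes went the other way, as Clca3a1 rose 3.52-fold. Adjusted over the list alone 6 members were lower and 2 higher, with log2 fold changes of -0.96 for Robo4, -0.93 for Tie1, -0.91 for Esam and -0.71 for Fgd5, and of 0.97 for Cd48, a marker of cells that have left the most immature stage. With the replicate block 4 members fell and 2 rose, and without wild-type replicate 1 the numbers were 9 and 2. With arrays centred on their medians, which adds the same amount to every gene, the list still passed (mean -0.02, camera adjusted p = 0.0288). Its call was lost without wild-type replicate 2 (mean -0.14, camera adjusted p = 0.125), wild-type replicate 3 (-0.11) or knockout replicate 1 (-0.13). The stem cell transcription factor list had a mean of -0.15 over 37 members and did not pass camera (adjusted p = 0.201). This mean lay at percentile 0 of the matched random lists, whose median was 0.20, so the list lay below genes of similar expression. Hlf fell, and adjusted over the list alone 4 members were lower and 1 higher, among them Ndn (-1.65), Mecom (-1.22), Prdm16 (-0.69) and Gfi1 (0.64). Without wild-type replicate 1 the mean was -0.33 (camera adjusted p = 6.07e-05), within a range of 1.28e-05 to 0.889 over 19 alternatives, and 9 members fell. With an estimated correlation the adjusted p of this list was 0.829 over 6 arrays and 0.528 without wild-type replicate 1, where no list passed (lowest adjusted p = 0.424). With the replicate block 3 members fell.

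NF-κB target genes, the list closest to the deleted factor, did not pass camera. Their mean log2 fold change was 0.08 over 60 members, the median was -0.06, and the camera direction was lower (adjusted p = 0.978), so these differed in sign. Of the 60, 4 rose and 0 fell: Lcn2, Irf8 (3.17-fold), Cd69 (2.51-fold) and Gadd45b (2.38-fold). Lcn2 and Irf8 are also genes of myeloid cells. Adjusted over the list alone 5 were higher and 1 was lower. The added ones were Il6 (log2 fold change 1.34) and the chemokine gene Ccl3 (-0.71). Il6 had a wild-type signal of 3.54, below that of Kdm5d (4.15), and a wide spread in knockout (SD 0.70). The size of its rise is therefore uncertain. With the replicate block 5 members of the list rose and 1 fell. That 0 fell over all genes depends on wild-type replicate 1. In its absence the mean was 0.03, 4 members rose and 2 fell, Ltb (-1.11) and Nfkbia (-0.72, limma adjusted p = 0.0334, and -0.43 over 6 arrays), and 7 rose and 4 fell adjusted over the list alone. Nfkbia, the gene of the inhibitor IκBα, is named here after its values were seen. Among NF-κB subunits and regulators 1 of 25 rose, Nfkbib, which encodes the inhibitor IκBβ (1.71-fold); the list's mean was 0.10 (camera adjusted p = 0.375) and turned negative without wild-type replicate 1, where Nfkbib rose and Rela and Nfkbia fell, and with cyclic loess normalization.

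The lymphoid list had a mean of -0.03 over 35 members, the megakaryocyte list of -0.11 over 24 and the erythroid list of 0.28 over 24, and none passed camera (adjusted p = 0.418, 0.723 and 0.079). The megakaryocyte mean lay at percentile 0 of the matched random lists, whose median was 0.23, and the erythroid mean at percentile 99.02. In these lists 0 members passed limma over all genes or adjusted over the list alone, and 7, 5 and 8 had an unadjusted p under 0.05. With the replicate block Mmrn1 (log2 fold change -1.38), a megakaryocyte gene, and Ltb (-0.85) fell, and Tfrc (1.45), the transferrin receptor gene, rose. The megakaryocyte mean was -0.30 without wild-type replicate 1 (camera adjusted p = 0.0504), with Mmrn1 and Ppbp lower, -0.22 without knockout replicate 3, and between -0.02 and -0.01 without wild-type replicate 2, wild-type replicate 3 or knockout replicate 1. The lymphoid mean was -0.08 without wild-type replicate 1, with Ltb and Cd3d lower, -0.14 without knockout replicate 2, and 0.04, 0.01 and 0.05 without wild-type replicate 3, knockout replicate 1 and knockout replicate 3. The erythroid mean was 0.16 without wild-type replicate 1, with Tfrc higher, and 0.17 without knockout replicate 1. Ppbp, a chemokine gene of platelets, was named after its values were seen. With centred arrays the lymphoid and megakaryocyte means were positive. The megakaryocyte list shifted lower under quantile (mean -0.25) and cyclic loess normalization (-0.30), and the erythroid list shifted higher without knockout replicate 2 (0.45, camera adjusted p = 0.000165). Quiescence and CDK inhibitor genes had a mean of 0.07 over 31 members (camera adjusted p = 0.295), which turned negative with cyclic loess normalization and without wild-type replicate 1. None of them passed limma over all genes, 8 had an unadjusted p under 0.05, and Ndn was lower adjusted over the list alone and with the replicate block.

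Smaller shifts were found in 5 other lists, and all 5 means lay inside the central 95% of the matched random lists, at percentiles 90.74 for DNA repair, 94.21 for oxidative stress defence, 89.97 for cytokine and Toll-like receptors, 46.48 for glycolysis and 75.35 for apoptosis. Random genes of similar expression thus shifted by similar amounts. DNA repair genes had a mean of 0.32 (camera adjusted p = 2.18e-05; adjusted p = 0.715 with an estimated correlation), with 0 members past limma over all genes, 8 at an unadjusted p under 0.05, and 2, Brca1 (log2 fold change 0.72) and Fancd2 (0.62), higher adjusted over the list alone. Oxidative stress defence genes had a mean of 0.33 (camera adjusted p = 0.000137; adjusted p = 0.715 with an estimated correlation), and Mt1 (metallothionein 1) rose 2.42-fold and Gsr (glutathione reductase) 1.96-fold. The cytokine and Toll-like receptor list (mean 0.18) and the glycolysis list (0.20) each had a camera adjusted p of 0.0414, and of 0.715 and 0.734 with an estimated correlation. In the first Cish fell, and adjusted over the list alone 5 members were higher and 2 lower. In the second Hk3 (hexokinase 3) rose 2.46-fold, and adjusted over the list alone 5 were higher and 1 lower. The apoptosis list had a mean of 0.18 and lay at the threshold (camera adjusted p = 0.05, below the threshold before rounding, and 0.715 with an estimated correlation), with Birc5 higher and 2 members higher adjusted over the list alone. Under quantile and cyclic loess normalization the means were 0.20 and 0.11 for DNA repair and 0.19 and 0.13 for oxidative stress defence, which kept their calls. They were 0.14 and 0.08 for the cytokine list, 0.10 and 0.04 for glycolysis and 0.12 and 0.06 for apoptosis, which lost them under both. Without wild-type replicate 1 the means were 0.13 for DNA repair and 0.18 for oxidative stress defence, which kept their calls, and 0.09, 0.07 and 0.07 for the cytokine, glycolysis and apoptosis lists, which lost them. The last 3 kept their calls under 11, 9 and 9 of 19 alternatives and also lost them without knockout replicate 2 (means 0.13, 0.16 and 0.16), and the apoptosis list did without knockout replicate 1 (0.18). The replicate block gave 3 higher and 2 lower members in the cytokine list, 2 higher in glycolysis and 2 higher in the apoptosis list.

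The remaining lists did not pass camera on the deposited values. Adhesion, homing and migration genes had a mean of 0.15, with Ccr2 higher and Tgm2 lower; adjusted over the list alone 3 were higher and 3 lower, and the replicate block gave 2 and 3. Its mean was 0.05 without wild-type replicate 1, with 3 members higher and 4 lower, 0.06 under quantile and 0.01 under cyclic loess normalization. The means were 0.06 for p53 targets, 0.06 for immediate early and heat shock genes, -0.08 for Notch, Wnt and hedgehog signalling and 0.09 for ribosomal proteins. The sign turned with cyclic loess normalization for the immediate early and ribosomal lists and with centred arrays for the signalling list. Adjusted over the list alone, Cebpd (0.91) was higher and Dusp1 (-0.61) lower among immediate early genes, of which 0 passed limma over all genes and 8 had an unadjusted p under 0.05, and 0 members passed limma either way in the other 3 lists, where 6 p53 targets, 8 signalling genes and 1 ribosomal gene had an unadjusted p under 0.05. The signalling list passed as lower without wild-type replicate 1 (mean -0.11, camera adjusted p = 0.0411, and 0.424 with an estimated correlation) and with array weights (-0.11, camera adjusted p = 0.0468), within a range of 0.0411 to 0.63 over 19 alternatives. The ribosomal list passed in both directions, higher with centred arrays (0.23) and without wild-type replicate 3 (0.13) and lower with cyclic loess normalization (-0.08), and its mean lay at percentile 0.1 of the matched random lists. These calls used the preset correlation, and with an estimated one over 6 arrays the list's camera adjusted p was 0.829. The p53 and immediate early means were -0.01 each without wild-type replicate 1.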

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

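The tests on mature neutrophils, mature macrophages, wild-type replicate 1 and a share of myeloid-committed cells, and the use of matched random lists, were chosen after the results they bear on, or the list means, had been seen.

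Some signal lay in rows outside the gene comparison. Of 1621 rows with several gene symbols, 1 passed limma over all rows and was higher in knockout, by 3.39 on the log2 scale. Of 12147 rows with no gene listed, 2 passed and were higher, the larger by 2.56.

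Beside the rise of 12 of 32 myeloid genes in knockout cells, late genes of mature neutrophils had a mean log2 fold change of -0.174 (SE 0.185 over 5 genes). They were S100a8, S100a9, Ltf, Camp and Ngp. S100a8 had 7.39 in wild-type and 7.81 in knockout. Complement genes of macrophages had a mean of -0.13 (SE 0.132 over 3). For the 3 complement genes, this argues against a larger share of mature macrophages, which lie outside the gate, as the cause. The 5 neutrophil genes, themselves in the myeloid list, ran from -0.71 (S100a9) to 0.42 (S100a8). Ltf, at 4.01 in wild-type and 3.71 in knockout, lay below the wild-type signal of Kdm5d (4.15), so its value is uncertain. Hp (3.86) and Lcn2 (2.71), described above with genes of neutrophil and monocyte precursors, were higher, as was Cxcr2 (1.14), a neutrophil gene. None of these is among the 5. Cxcr2 did not pass over all genes (limma adjusted p = 0.0531). The 5 genes thus do not settle the share of neutrophils. The myeloid mean was 1.02 without wild-type replicate 1, against 1.06 with it, which argues against that array as the whole cause. It was 0.99 under quantile normalization, which gives all arrays the same range of values. That argues against the signal range as the whole cause. The mean also lay at percentile 100 of 10000 random lists matched on expression, which is descriptive. A larger share of myeloid-committed cells inside the gate and a change within each cell cannot be told apart, since stem cell genes could be lower under either. Their mean was -0.29 over 72 genes without wild-type replicate 1, but over all 6 arrays the transcription factor and surface lists were at -0.148 and -0.168. Only 1 of 10 splits of the 6 arrays into 3 and 3, the real one, called as many as 163 genes with limma (4309 at an unadjusted p under 0.05). The highest of the others, among them 3 that also part all the numbered pairs, called 0 (104 to 674 genes at an unadjusted p under 0.05). However, 10 splits are too few for a share under 0.05. Mature monocytes and basophils or mast cells were not tested. A sort for lineage-negative, c-kit-positive and Sca-1-positive cells should remove mature monocytes and basophils. These cells and the p65 deletion stay among the open explanations.

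The trend of fold change with expression could account for shifts of lists made of bright or dim genes. Against matched random lists, the means lay at percentile 100 for the cell cycle, 99.96 for the respiratory chain, 100 for interferon-stimulated genes and 98.39 for MHC class I presentation. They lay at 100 for mast cell genes, 0.16 for B, plasma, T and NK cell markers and 0 for stem cell surface genes. These means thus lay beyond those of most random lists of similar expression. The trend together with joint variation of a list's genes is not excluded. No list passed camera with an estimated correlation (lowest adjusted p = 0.434). DNA repair at 90.74, oxidative stress defence at 94.21, macrophage and granulocyte markers at 3.27, glycolysis at 46.48, apoptosis at 75.35, cytokine and Toll-like receptors at 89.97 and MHC class II at 97.3 lay within the central 95%, as the trend would give. Of lists that did not pass camera, stem cell transcription factors (0), megakaryocyte (0), ribosomal (0.1) and erythroid genes (99.02) lay outside it. Genes of a list vary together and random genes do not, so these percentiles are not p-values, and proliferation that differs between genotypes stays open, untested.

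The stem cell transcription factor list passed camera without wild-type replicate 1 (mean log2 fold change -0.33) and not with it, at the preset correlation; with an estimated one it passed in neither (adjusted p = 0.528 and 0.829). Over its 37 genes that array lay 0.545 below the other wild-type arrays (a difference of -0.545 on the log2 scale), at percentile 0 of matched random lists. Random genes are drawn independently while genes of a list vary together, so this percentile cannot decide whether the narrower range alone placed that array there. A difference in the cells of that sort may remain, and it was not tested.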

How the results depend on the processing

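Cyclic loess normalization was chosen after the data were seen. Centring adds 0.146 to every fold change, so a sign it turns does not bear on a list relative to other genes. The 163 genes kept their direction in each scaling. Centring could not have turned a sign, since all 163 differ by at least 1.5-fold. Leaving out 1 array could not turn a sign, since the groups do not overlap in any of these genes. Calls kept numbered 163 without wild-type replicate 1, 90 with quantile normalization, 141 with centred arrays and 114 with cyclic loess. Only 59 and 26 were kept without wild-type replicates 2 and 3, and 22, 21 and 29 without knockout replicates 1, 2 and 3. Of list and named-gene values, 428 and 1409 stayed on the same side of the threshold and in the same direction, while 70 and 249 lost a call, 14 and 145 gained one, and 20 and 13 changed sign. Causes were not tested unless stated. A covariate for sex was not run because the arrays gave no sign of both sexes, and a pseudocount does not apply to log2 values. Signal over background was not analysed here, so what dim signals limit was not measured.

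Numbers of genes past limma (total, higher, lower) were 372, 282 and 90 with the replicate block, and 505, 424 and 81 without the dimmest genes, where fewer genes are tested. Array weights gave 1599, 1117 and 482. Quantile normalization gave 104 and 86 higher, centred arrays gave 6 lower and cyclic loess 70 lower. All rows of the table gave 22, 22 and 0 (6037 rows at an unadjusted p under 0.05). The ordinary per-gene test gave 0, 0 and 0 (3497 genes at an unadjusted p under 0.05). Leaving out 1 array gave 21 to 929, 21 to 653 and 0 to 276. The lower count was 0 without each knockout array, with 2697, 2419 and 2280 genes at an unadjusted p under 0.05. Genes with at least 1.5-fold at p under 0.01 numbered 692 with quantile normalization, 698 with cyclic loess and 575 to 1510 without 1 array, and 206 at a 2-fold minimum.

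Rela was -0.4918 (limma adjusted p = 0.0292) with array weights, -0.6128 (adjusted p = 0.0374) with cyclic loess and -0.5148 to -0.3123 without 1 array, against -0.3856 with the replicate block (adjusted p = 0.184). Flt3 changed sign with quantile normalization (-0.0967), array weights (-0.1227) and cyclic loess (-0.1786), and ran from -0.0926 to 0.2894 without 1 array. Cd34 did with quantile normalization (-0.1459) and cyclic loess (-0.1891), and ran from -0.0698 to 0.1016. Nfkb2 did with weights (-0.0434) and cyclic loess (-0.0368), and ran from -0.0687 to 0.1011. Rel ran from -0.00255 to 0.4068.

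An estimated correlation left 0 lists past the threshold, and fry 1, against 15. All 15 lost their call under the first, among them stem cell surface (-0.1676), cell cycle (0.6182), interferon (0.6319) and myeloid (1.064), whose means these tests leave as they are, and all but the myeloid list lost it under fry. Without 1 array the number was 11 to 15. Stem cell transcription factors passed with quantile normalization (-0.2488), dim genes left out (-0.15), weights (-0.3041) and cyclic loess (-0.3051), and ran from -0.33 to -0.0305 without 1 array. Stem cell surface ran from -0.2472 to -0.1131, erythroid from 0.1554 to 0.4463. The megakaryocyte list was -0.2454 with quantile normalization, -0.2995 with cyclic loess and 0.0379 with centred arrays, and ran from -0.2968 to -0.0054 without 1 array. The lymphoid list was 0.1185 with centred arrays, 0.044 without dim genes, 0.0302 as a median and -0.1433 to 0.0511 without 1 array. NF-κB targets had a median of -0.059. NF-κB subunits were -0.0322 with weights, -0.0425 with cyclic loess and -0.0607 to 0.1805 without 1 array. Quiescence was -0.0481 with weights, -0.0562 with cyclic loess and -0.0565 to 0.1702. Immediate early genes were -0.00646 with weights, -0.0469 with cyclic loess and -0.00711 to 0.1227. The p53 list ran from -0.00801 to 0.0975. Notch, Wnt and hedgehog signalling was 0.0649 with centred arrays, and ran from -0.1118 to -0.0522 without 1 array, passing without wild-type replicate 1 (camera adjusted p = 0.0411) and with weights (-0.1114, adjusted p = 0.0468). Ribosomal proteins were -0.0833 with cyclic loess (camera adjusted p = 0.0141) and 0.0622 to 0.1267 without 1 array, and passed as higher with centred arrays (0.2335, adjusted p = 0.0055), an intensity trend (0.0255), ranks (0.0394) and without wild-type replicate 3 (0.042). The replicate block changed no list's call. Among named genes it added Mcpt8 (1.779), Tfrc (1.451), Il6 (1.341), Prss34 (1.306), Csf2rb (1.242), Cxcr2 (1.143), Cd48 (0.9746), Cycs (0.9123), Ifngr1 (0.8557) and Pfkp (0.7791) as higher. It added Il18r1 (-0.7618), Ltb (-0.8502), Esam (-0.9077), Tie1 (-0.9341), Robo4 (-0.9563), Mecom (-1.222), Mmrn1 (-1.378), Emcn (-1.481) and Ndn (-1.651) as lower, and changed no other call of a named gene. Counts of members it moved by over 1.5 times stand beside the lists. The wild-type signal of Il6 lay below that of Kdm5d, so the size of its rise is uncertain.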

Other observations

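The gene lists in this part were written after the called genes had been seen. A few of their members also sit in lists whose summaries were known, and Ndn, Calr, Canx and Pdia3 are named genes with values of their own. Both tests were therefore chosen after the result, and both hypotheses were found and tested on the same data.

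Several genes of protein folding in the endoplasmic reticulum were among the genes that rose, chosen here after their values were seen, such as Sdf2l1 (log2 fold change 1.20), Ero1a (1.17) and Hyou1 (0.91). A list of 33 other measured genes of folding and translocation in this compartment, without the 8 already called, had a mean log2 fold change of 0.64 (SE 0.03 over genes), and 33 of 33 were positive. That mean lay at percentile 100 of 10000 random lists matched on expression. Of these genes 29 had an unadjusted p under 0.05, and 12 rose without wild-type replicate 1, where the mean was 0.50. The camera p was 2.29e-18 with a preset correlation and 0.0979 with an estimated one, and the mean was 0.41 under quantile and 0.38 under cyclic loess normalization. Dnajb11 had the largest value (1.07) and Hspa5, the chaperone BiP, had 0.76.

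Meg3, an imprinted gene, was among the genes that fell. A list of 26 other measured imprinted genes had a mean log2 fold change of -0.38 (SE 0.07 over genes), with 24 negative, at percentile 0 of the matched random lists. Of these genes 8 had an unadjusted p under 0.05, where 4309 of all 19938 genes did. Ndn, a named gene, fell the most of the 26 (-1.65). The mean was -0.34 without wild-type replicate 1, where 5 fell, among them Ndn (-1.86), Sgce (-0.72) and Airn (-0.73). The camera p was 1.13e-05 with a preset correlation and 0.00798 with an estimated one, and the mean was -0.24 under quantile, -0.25 under cyclic loess normalization and -0.23 with centred arrays. Lower expression of imprinted genes in these sorted knockout cells is a hypothesis that other samples could test, and a change in the mix of cells may give the same values.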
